A study of Mus musculus with 43 samples.

How the data were processed

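Polyadenylated RNA from 43 samples of mouse embryonic fibroblasts (MEF) was extracted with a PureLink kit and sequenced as stranded TruSeq mRNA libraries, per the labels. The libraries fall into 13 groups in 3 systems. In the siRNA system (4 groups of 4 libraries) cells carried a control siRNA or a siRNA against Son and received the solvent DMSO or tunicamycin. In the CRISPRa system (4 groups of 3 libraries) cells carried a control guide RNA or a Son guide RNA (sgRNA) for CRISPR activation, again with DMSO or tunicamycin. In the drug system (5 groups of 3 libraries) wild-type cells received DMSO, 3 µM nintedanib, 1 µM ponatinib, 3 µM proflavine hemisulfate or 1 µM pyrvinium pamoate for 24 h. The dose and duration of tunicamycin are not given in the sources used here.

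The authors deposited the siRNA and CRISPRa libraries as a table of FPKM (fragments per kilobase of transcript, scaled to library size) for 28 libraries. The authors deposited the drug libraries as a table of TPM (transcripts scaled to transcript length and to a fixed library total) for 15 libraries. Both units are those in the titles of the deposited tables. The submitters' processing notes name the mouse build mm10 and the tools Trimmomatic, Trim Galore, HISAT2, Salmon and Cufflinks. Which tool made which table, the versions and settings of these tools and the gene annotation are not given in the sources used here. Each table was tested within itself. The FPKM columns name the group and carry a letter, so libraries of these systems are called by letter and cannot be tied to the numbers in the labels. Columns headed for a scrambled control were taken as the control siRNA groups, and the only other control columns, of the same number as the control sgRNA samples, as the control sgRNA groups.

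With FPKM values, 275 symbols stood on 807 lines, and for each the line with the highest mean in the system was kept. A further 27 entries had been turned into dates, 17 of them with a mean of at least 1, and were left out. This left 24327 symbols with FPKM values and 25080 with TPM values. Symbols with a mean of at least 1 over the libraries of a system were tested, which gave 10883 genes in the siRNA system, 11218 in the CRISPRa system and 12132 in the drug system. Coordinates are those of the GENCODE annotation of GRCm38 (mm10), matched by symbol, and transcript length is that of the longest annotated transcript.

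Values were taken as log2(value + 1), a scale that understates the change of genes with low values. Fold changes and counts of genes changed at least 2-fold are on this scale. A gene whose mean level rose 2-fold may therefore not be counted. A linear model per system was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a mean trend), with a term per group and no block. From the 3 fits 14 comparisons were read. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05, adjusted within each comparison. The tests are two-sided. The differences of the tunicamycin responses between the Son and control arms were tested as interaction terms. The p-values measure only the spread between these samples, since the labels do not state that the libraries came from separate cultures.

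The comparisons, tests, 25 gene lists and 7 lists of cell type markers were fixed before the data were examined. Of these lists 3 had too few measured genes to be tested in any system. Lists were tested against all other genes with camera at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. These tests were adjusted together over all lists and comparisons of a system, with 26 lists per comparison in the FPKM systems and 28 in the drug system. None of the list calls held with the estimated correlation, and the adjusted p with that correlation is given with each list. This includes the list of ATF4 and integrated stress response genes in tunicamycin with control siRNA, where all measured genes rose. Failing this test therefore does not by itself tell against a list. Limma's fry, which tests a list without the other genes, was run as well. It called from 2 of 26 lists (difference of responses in the CRISPRa system) to 28 of 28 (nintedanib), and 20 of 26 for tunicamycin with control siRNA. Counts within a list come from the adjustment over all genes and, in brackets, from that over the list alone.

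Genes named in the text follow a rule fixed with the lists. It takes Son and 11 fixed genes, and the 5 raised and 5 lowered genes of largest change among those called, with a mean of at least 5 in the higher group and every library of one group above every library of the other. Lines without a symbol, predicted genes and pseudogenes were passed over. It also takes up to 4 called members of largest change from each called list. For the differences of tunicamycin responses the condition on overlap was dropped. Some genes that this rule gives are not reported here. The Xist and Rn45s levels were chosen after their values were seen.

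The overlap of drug responses was set beside 100 simulated draws of unchanged groups against the same controls. Sets of up to 200 genes raised or lowered with Son siRNA or in the libraries labelled Son sgRNA were tested in the drug comparisons with camera. Alternatives chosen beforehand were a pseudocount of 0.1, no filter on low values, a mean of at least 5, median-ratio scaling, quantile normalization, no mean trend, array weights (statmod 1.5.0), a replicate block for the drugs, only the groups compared, sets of at most 50 genes, and each library left out in turn. After the data had been seen, 4 alternatives were added: all lines of each symbol, the removal of a smooth trend on transcript length, a block on the letter of the FPKM columns, and the CRISPRa fit without the 2 libraries that stood apart.

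Each fit was tested on simulated data with 200 genes changed by known folds. Of 50 genes changed 1.5-fold, 100% were recovered in the comparison of Son siRNA with control in DMSO (10883 genes) and 84% in that of Son sgRNA with control in DMSO (11218 genes). For the difference of tunicamycin responses the shares were 98% with Son siRNA and 64% with Son sgRNA, and 100% and 86% at 2-fold. In the drug comparisons (12132 genes) 92% to 96% were recovered at 1.5-fold. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

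FPKM and TPM carry no read totals, so the absolute depth is unknown. In the FPKM table the lowest values of a gene in 2 libraries stood in ratios of small whole numbers for 78.5% to 84.8% of the values (within 0.02 on the log2 scale), which gives the depth of each library relative to library A of the control siRNA group in DMSO. It ranged from 0.908 to 1.206 in the siRNA system and from 0.933 to 1.129 in the CRISPRa system. TPM keeps no depth, and its column sums ran from 952123 to 989105. No pair of libraries held identical values.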

Results

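RNA levels were measured in 43 libraries of mouse embryonic fibroblasts to compare cells with altered Son, with and without tunicamycin, and wild-type cells given 1 of 4 drugs. Son is a large RNA-binding protein of nuclear speckles that takes part in pre-mRNA splicing. Tunicamycin blocks N-linked glycosylation and so causes stress of the endoplasmic reticulum (ER). The siRNA groups had 4 libraries each. The groups with a guide RNA for CRISPR activation (CRISPRa) and the drug groups had 3 each. Errors beside levels are SDs and those beside log2 fold changes are standard errors (SE). Summed FPKM ran from 393764 to 424082 per library in the siRNA system and from 381968 to 499908 in the CRISPRa system, and summed TPM from 952123 to 989105. Xist, the RNA that silences an X chromosome in female cells, had group means of 27.4 to 32.4 FPKM in the siRNA system and at most 0.00396 FPKM in the CRISPRa system. The cells of these systems thus differed in Xist.

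Son (chromosome 16, 91647506 to 91679221, mm10) was measured in every library as a check of the labels. With control siRNA it stood at 43.5 ± 0.979 FPKM in DMSO and 36.0 ± 0.908 FPKM in tunicamycin (n = 4 each). With Son siRNA it fell to 21.8 ± 0.970 FPKM in DMSO (log2 fold change −0.97, SE 0.043, adjusted p = 7.04e-10) and to 15.4 ± 1.14 FPKM in tunicamycin (−1.17, SE 0.043, adjusted p = 3.11e-11), with each library below every control library. In this system tunicamycin itself lowered Son with control siRNA (−0.26, SE 0.043, adjusted p = 3.29e-05) and with Son siRNA (−0.47, SE 0.043, adjusted p = 6.13e-08). In the CRISPRa system Son did not go the way its guide RNA is labelled. It stood at 47.4 ± 0.971 FPKM in the control sgRNA libraries in DMSO and at 51.9, 44.6 and 29.8 FPKM in libraries A, B and C labelled Son sgRNA (log2 fold change −0.20, SE 0.156, adjusted p = 0.383). In tunicamycin it stood at 42.4 ± 1.29 FPKM with control sgRNA and at 45.3, 35.0 and 42.4 FPKM in libraries A, B and C labelled Son sgRNA (−0.059, SE 0.156, adjusted p = 0.897). The comparisons of these libraries are therefore described by their label, since no rise of Son RNA was detected behind it. With these SEs a small rise is not excluded. Between DMSO and tunicamycin Son was not called in the libraries labelled Son sgRNA, but was without library C in DMSO (−0.24, adjusted p = 0.0405). Among the drugs, pyrvinium lowered Son from 98.4 ± 1.33 TPM in DMSO to 69.3 ± 6.41 TPM (−0.50, SE 0.088, adjusted p = 9.74e-05, n = 3). Nintedanib lowered it to 84.7 ± 13.3 TPM (−0.23, SE 0.088, adjusted p = 0.0406), where library 1 had 69.4 TPM and the others 93.5 and 91.2 TPM. That call was lost without nintedanib library 1, at −0.091. It was also lost without DMSO library 1 (−0.21, adjusted p = 0.0962), 2 (−0.23, adjusted p = 0.0738) or 3 (−0.23, adjusted p = 0.0772), ponatinib library 2 (−0.23, adjusted p = 0.0509) or proflavine library 2 or 3 (−0.23, adjusted p = 0.0508 and 0.0501). Ponatinib (89.7 ± 3.38 TPM, adjusted p = 0.206) and proflavine (98.2 ± 2.05 TPM, adjusted p = 0.985) did not pass the test. Without nintedanib library 1, Son with ponatinib passed it (−0.13, adjusted p = 0.0411). It also passed under median-ratio scaling (−0.25), quantile normalization (−0.18), array weights (−0.13), with only the 2 groups compared (−0.13) and with the length trend removed (−0.24). With the length trend removed Son with proflavine was called higher (0.108, adjusted p = 0.00588).

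**Figure D1:**
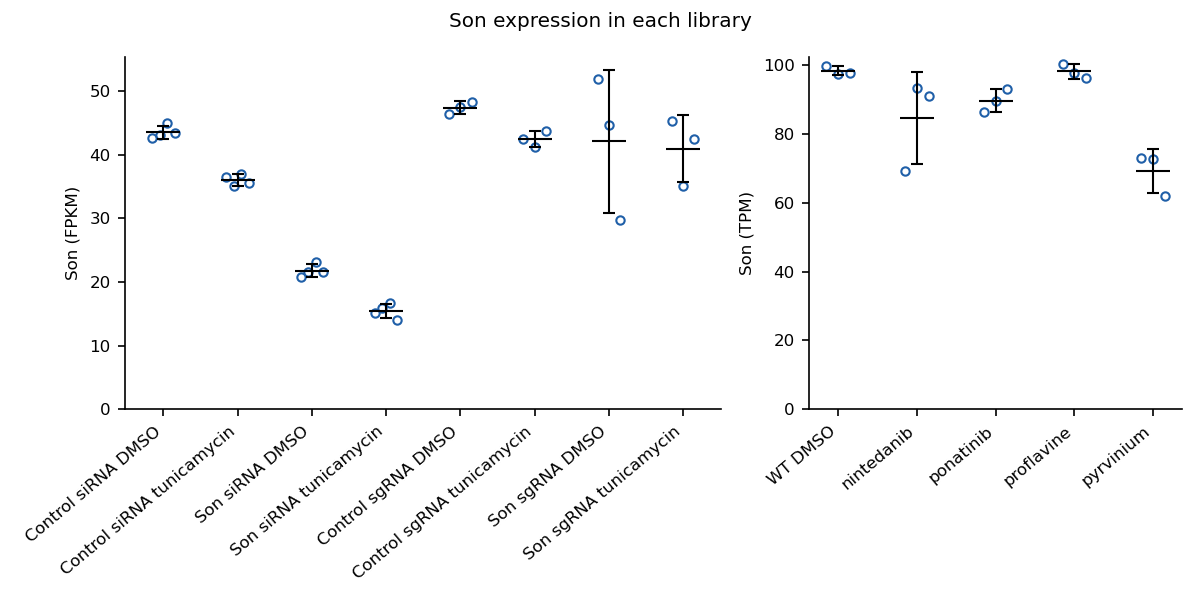
Son level in each library, in FPKM for the siRNA and CRISPRa groups (left panel) and in TPM for the drug groups (right panel), with circles for libraries and bars for the mean and SD of each group. The 8 libraries with Son siRNA lie below every control siRNA library, while those labelled Son sgRNA run from 29.8 to 51.9 FPKM around their controls.

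Interferon-response genes fell together when Son was lowered by siRNA in DMSO. Dhx58, a cytosolic RNA sensor of the RIG-I family (chromosome 11, 100694884 to 100704271), fell from 31.6 ± 3.35 to 14.2 ± 1.98 FPKM (log2 fold change −1.10, adjusted p = 3.84e-07, n = 4). Ifit3, an interferon-induced antiviral gene, fell from 96.9 ± 8.65 to 46.6 ± 9.77 FPKM, and Irf7, a transcription factor of the interferon response, from 91.9 ± 10.5 to 50.8 ± 5.78 FPKM. Of the 33 measured genes of the interferon list, 31 fell and none rose (33 fell adjusted over the list alone), with a median log2 fold change of −0.60 (camera adjusted p = 1.01e-21, adjusted p = 0.63 with an estimated correlation). Of 11 genes reported elsewhere to need SON for splicing, 8 fell (8 adjusted over the list alone; median −0.32, adjusted p = 2.05e-06, adjusted p = 0.166 with an estimated correlation). Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, went from 18.6 ± 0.700 to 10.7 ± 0.410 FPKM. Idh2, the mitochondrial isocitrate dehydrogenase, went from 97.7 ± 1.62 to 62.0 ± 1.51 FPKM (−0.65, SE 0.031, adjusted p = 1.02e-09), and Shmt2 from 81.1 to 50.6 FPKM. Pck2, Shmt2 and the amino acid transporter Slc7a5 (−0.62, SE 0.069) are ATF4 targets. Of 39 genes of the ATF4 and integrated stress response list 14 fell and 4 rose (15 and 4 adjusted over the list alone; median −0.061, adjusted p = 0.0183, adjusted p = 0.822 with an estimated correlation; −0.033 without library B of Son siRNA in DMSO). The speckle protein gene Srrm2 rose slightly, from 55.0 ± 0.899 to 63.5 ± 2.70 FPKM (0.20, SE 0.030, adjusted p = 5.44e-05). Akap8l (0.64), Fbxo17 (0.64), Prr3 (0.63) and Tnfrsf9, a receptor of the TNF family (0.66), had the largest rises named here. Atf4 (−0.022, adjusted p = 0.695), Ddit3 (0.055, adjusted p = 0.54) and Trib3 (0.027, adjusted p = 0.641) did not pass the test. In all, 3923 of 10883 genes changed, 2172 up and 1751 down, of which 6 changed at least 2-fold.

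In tunicamycin, ER stress genes and interferon genes were lower with Son siRNA. Creld2, an ER-resident protein, stood at 502.3 ± 98.4 FPKM with control siRNA and 323.6 ± 11.2 FPKM with Son siRNA (log2 fold change −0.61, SE 0.086, adjusted p = 1.91e-05, n = 4). Library D of control siRNA stood apart with Creld2 at 648.7 FPKM (438.8 to 469.3 in the others), and without it the log2 fold change was −0.49 (adjusted p = 8.4e-08). Derl3, part of the machinery that degrades misfolded ER proteins, stood at 24.7 ± 6.21 and 13.03 ± 0.703 FPKM. Syvn1, a ubiquitin ligase of the same pathway, stood at 114.5 ± 15.2 and 79.8 ± 1.76 FPKM, and Dnajb9, an ER co-chaperone, at 63.7 ± 10.0 and 42.4 ± 1.95 FPKM. Hspa5, the main ER chaperone BiP, fell by 0.32 (SE 0.081, adjusted p = 0.00315), a call lost under quantile normalization (−0.15). Ddit3, which encodes the stress transcription factor CHOP, fell by 0.31 (SE 0.066, adjusted p = 0.00102). Among ER chaperones 19 of 27 fell and none rose (20 fell adjusted over the list alone; median −0.26, adjusted p = 1.46e-06, adjusted p = 0.67 with an estimated correlation; −0.18 without library D). In the list of ER translocation and degradation 20 of 41 fell and 1 rose (20 and 1 adjusted over the list alone; median −0.11, adjusted p = 1.65e-05, adjusted p = 0.67 with an estimated correlation). In the ATF4 list 25 of 39 fell and none rose (25 adjusted over the list alone; median −0.16, adjusted p = 2.93e-06, adjusted p = 0.67 with an estimated correlation; −0.10 without library D of control siRNA in tunicamycin). Interferon genes fell here too, 32 of 33 with a median of −0.67 (32 adjusted over the list alone; adjusted p = 1.22e-17, adjusted p = 0.638 with an estimated correlation). Mitotic genes were higher, with 23 of 28 raised and none lowered (23 adjusted over the list alone; median 0.18, adjusted p = 2.11e-06, adjusted p = 0.644 with an estimated correlation), among them Bub1 (0.34, SE 0.035) and Mki67 (0.30, SE 0.050). Of 42 nuclear genes of oxidative phosphorylation 25 rose and 2 fell (25 and 2 adjusted over the list alone; median 0.10, adjusted p = 0.0023, adjusted p = 0.67 with an estimated correlation; 0.066 with the length trend removed). Neat1, the long non-coding RNA that builds paraspeckles, fell from 68.2 ± 6.93 to 30.6 ± 3.83 FPKM. Pck2 fell from 84.8 ± 7.43 to 43.8 ± 1.55 FPKM and Idh2 from 82.6 ± 2.09 to 47.0 ± 2.16 FPKM, while Tnfrsf9 rose from 5.57 ± 0.814 to 11.6 ± 1.22 FPKM. The cell cycle inhibitor Cdkn1a fell by 0.45 (SE 0.071, adjusted p = 6.55e-05). Across all genes 5552 of 10883 changed, 3328 up and 2224 down, 11 of them at least 2-fold. Atf4 (−0.062, adjusted p = 0.196) and Trib3 (−0.061, adjusted p = 0.227) did not pass the test.

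Tunicamycin raised the ER stress genes strongly in the control siRNA cells. Herpud1, an ER membrane protein of the degradation pathway (chromosome 8, 94386438 to 94395377), rose from 17.7 ± 0.647 to 729.9 ± 80.2 FPKM (log2 fold change 5.28, SE 0.055, adjusted p = 1.77e-20, n = 4). Ddit3 (chromosome 10, 127290774 to 127296288) rose from 19.5 ± 2.33 to 543.1 ± 39.6 FPKM, Hspa5 (chromosome 2, 34771970 to 34777547) from 394.0 ± 18.9 to 4676 ± 681 FPKM, and the pseudokinase gene Trib3 from 7.64 ± 0.576 to 160.2 ± 4.35 FPKM. Atf4 rose 4.30-fold and Xbp1, the transcription factor activated by IRE1 splicing, 5.14-fold. All 39 genes of the ATF4 list rose (39 adjusted over the list alone; median 2.10, adjusted p = 2.64e-34, adjusted p = 0.166 with an estimated correlation). So did 26 of 27 ER chaperones (27 adjusted over the list alone; median 1.253, adjusted p = 1.66e-17, adjusted p = 0.608 with an estimated correlation). Mitotic genes fell, 28 of 28 with a median of −0.42 (28 adjusted over the list alone; adjusted p = 1.81e-09, adjusted p = 0.638 with an estimated correlation), among them the kinases Cdk1 (−0.69, SE 0.037) and Plk1 (−0.64, SE 0.031). Of 34 extracellular matrix and myofibroblast genes 30 fell and 1 rose (30 and 1 adjusted over the list alone; median −0.42, adjusted p = 3.76e-06, adjusted p = 0.667 with an estimated correlation), including Thbs1 (64.7 ± 1.95 to 18.8 ± 4.32 FPKM) and Ctgf (29.99 ± 0.790 to 8.82 ± 2.03 FPKM). All 7 fibroblast marker genes fell as well (7 adjusted over the list alone; median −0.50, adjusted p = 0.00848, adjusted p = 0.667 with an estimated correlation). Cholesterol synthesis genes went down, 20 of 24 against 2 raised (20 and 2 adjusted over the list alone; median −0.52, adjusted p = 3.75e-05, adjusted p = 0.667 with an estimated correlation). Glycolysis and hypoxia genes did so too, 20 of 24 against 2 raised (21 and 2 adjusted over the list alone; median −0.53, adjusted p = 0.00108, adjusted p = 0.735 with an estimated correlation), with the lactate transporter Slc16a3 falling from 46.3 ± 9.61 to 18.0 ± 4.13 FPKM. The stress-induced Gadd45a rose 7.92-fold and Cdkn1a 1.73-fold, and the clock gene Arntl 1.26-fold. Of 10883 genes 7504 changed, 2891 up and 4613 down, 304 at least 2-fold. The share raised was 38.5% and moved to 49.4% under median-ratio scaling and 50.4% with the length trend removed.

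With Son siRNA the tunicamycin response of the stress genes went the same way. Outside the ER chaperone list the response was smaller for 879 of 1162 genes that moved by at least 0.5 on the log2 scale. The median ratio was 0.874 (0.938 without control siRNA library D in tunicamycin). Herpud1 rose from 20.8 ± 0.838 to 649.1 ± 16.1 FPKM (4.90, SE 0.055, adjusted p = 6.11e-20, n = 4), Ddit3 from 20.2 ± 0.895 to 437.7 ± 16.5 FPKM and Hspa5 from 343.4 ± 22.5 to 3718 ± 313 FPKM. All 39 ATF4 genes rose (39 adjusted over the list alone; median 2.06, adjusted p = 1.34e-35, adjusted p = 0.166 with an estimated correlation). Among ER chaperones 24 of 27 rose (25 rose and 1 fell adjusted over the list alone; median 1.09, adjusted p = 2.53e-15, adjusted p = 0.63 with an estimated correlation). Of 28 mitotic genes 27 fell (27 adjusted over the list alone; median −0.36, adjusted p = 1.27e-07, adjusted p = 0.638 with an estimated correlation). In total 7314 genes changed, 2840 up and 4474 down, 217 at least 2-fold. The share raised, 38.8%, was 49.4% with the length trend removed. The difference between the 2 responses was tested directly. It passed for 183 genes (2071 at an unadjusted p under 0.05), 90 with a positive and 93 with a negative log2 difference (Son siRNA minus control siRNA), none of which differed by 2-fold. Lower responses were seen for Dnajb9 (log2 difference −0.47, SE 0.102, adjusted p = 0.0329), the ER oxidase Ero1lb (−0.47), Syvn1 (−0.42), Herpud1 (−0.38) and Bcat2, a branched-chain amino acid transaminase (−0.51, SE 0.085, adjusted p = 0.0187). Differences were positive for Oaf (0.54, SE 0.081, adjusted p = 0.0141) and the basement membrane gene Nid1 (0.53), which fell less with Son siRNA. Oaf fell from 25.5 to 5.692 with control siRNA and from 26.5 to 9.085 FPKM with Son siRNA. For Nid1 these levels were 52.88 to 21.08 and 60.35 to 34.92 FPKM. As a group 27 ER chaperones had a lower response, with 4 called and none higher (18 adjusted over the list alone; median −0.24, adjusted p = 3.78e-13, adjusted p = 0.638 with an estimated correlation). The median was −0.15 without control siRNA library D in tunicamycin, and the number called ranged from 0 without library B of Son siRNA in DMSO to 9 without that library D. The 28 mitotic genes had a positive difference, as their list fell less with Son siRNA. Of these, 1 was called (15 adjusted over the list alone, median 0.13, camera adjusted p = 1.19e-08, adjusted p = 0.638 with an estimated correlation). Hspa5 (−0.12, adjusted p = 0.581) and Ddit3 (−0.36, adjusted p = 0.0574) did not pass this test. The count of 183 became 43, 322, 55 or 79 without library A, B, C or D of control siRNA in DMSO, 107, 24, 48 or 47 without library A, B, C or D of Son siRNA in DMSO, and 46, 66 or 37 without library A, B or D of Son siRNA in tunicamycin. The calls of Herpud1 and Syvn1 were each lost in 8 of the 16 fits that left out 1 library, those of Dnajb9 in 9, Ero1lb in 6 and Nid1 in 5.

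**Figure D2:**
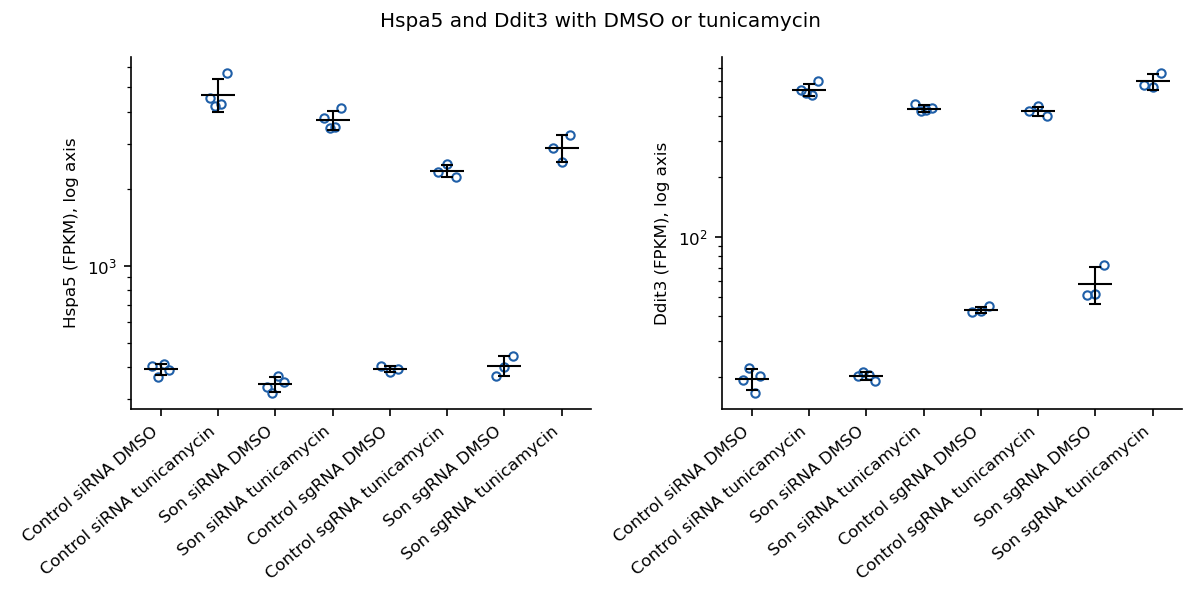
Levels of Hspa5 (left panel) and Ddit3 (right panel) in each library of the siRNA and CRISPRa groups, in FPKM on log axes, with circles for libraries and bars for the mean and SD of each group. With tunicamycin Hspa5 stands at 4676 FPKM with control siRNA and 3718 FPKM with Son siRNA, against 394.0 and 343.4 FPKM in DMSO.

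In the CRISPRa system, genes of the extracellular matrix fell in the libraries labelled Son sgRNA in DMSO. Col3a1, a fibrillar collagen (chromosome 1, 45311538 to 45349706), fell from 95.8 ± 4.43 to 27.1 ± 2.36 FPKM (log2 fold change −1.78, SE 0.145, adjusted p = 1.7e-05, n = 3). The matrix metalloproteinases Mmp3 (12.8 ± 0.957 to 1.99 ± 0.621 FPKM) and Mmp13 (9.84 ± 0.383 to 2.67 ± 0.335 FPKM), the collagen crosslinking enzyme Lox (243.2 ± 6.59 to 117.4 ± 12.98 FPKM) and the matrix glycoprotein Thbs2 (13.03 ± 1.19 to 3.64 ± 0.383 FPKM) fell too. Of 33 measured matrix and myofibroblast genes 19 fell and 2 rose (21 and 2 adjusted over the list alone; median −0.42, adjusted p = 8.51e-14, adjusted p = 0.157 with an estimated correlation). Of 8 fibroblast markers 4 fell and 1 rose (4 and 1 adjusted over the list alone; median −0.21, adjusted p = 0.0165, adjusted p = 0.346 with an estimated correlation), and the mesenchymal transcription factor gene Prrx1 stood at −0.69 (SE 0.080, adjusted p = 0.000231). Higher were creatine kinase B, Ckb (2.45 ± 0.422 to 7.21 ± 0.317 FPKM), the lysosomal glycoprotein gene Gpnmb (16.6 ± 0.465 to 34.9 ± 2.92 FPKM) and the invariant chain gene Cd74 (82.7 ± 8.65 to 151.1 ± 16.04 FPKM). Autophagy and lysosome genes rose, 9 of 44 against 2 that fell (14 and 2 adjusted over the list alone; median 0.145, adjusted p = 0.00111, adjusted p = 0.598 with an estimated correlation), a call lost under quantile normalization (median 0.057, adjusted p = 0.133). So did 5 of 24 p53 targets (8 adjusted over the list alone; median 0.13, adjusted p = 0.0053, adjusted p = 0.405 with an estimated correlation), among them Btg2 (0.43, SE 0.053) and Mdm2 (0.33, SE 0.060). Ddit3 passed the test (0.41, SE 0.117, adjusted p = 0.037), a call lost with no filter on low values, under median-ratio scaling, with only the 2 groups compared, without any 1 control sgRNA library in either condition and without library A labelled Son sgRNA in tunicamycin. Hspa5 did not pass (0.037, adjusted p = 0.835). In all, 1615 of 11218 genes changed, 1022 up and 593 down, 44 at least 2-fold. Library C labelled Son sgRNA stood apart, with a column sum of 499908 against 381968 to 425295 in the other libraries, and the log2 fold changes followed transcript length (Spearman −0.41 across genes, which are not independent replicates). Without it and library B labelled Son sgRNA in tunicamycin, a choice made after the data were seen, 3236 genes changed and the matrix genes had a median of −0.38. With the length trend removed the matrix median was −0.43 and that of the lysosome genes 0.090. The count was 891, 739 or 755 without control sgRNA library A, B or C in DMSO and 2640 without library A labelled Son sgRNA in DMSO. The share raised went from 63.3% to 47.1% under median-ratio scaling and 47.8% with the length trend removed.

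In tunicamycin the matrix genes were again lower in the libraries labelled Son sgRNA. Col3a1 stood at 76.9 ± 4.22 FPKM with control sgRNA and 19.0 ± 4.98 FPKM in these libraries (log2 fold change −2.00, SE 0.145, adjusted p = 7.51e-06, n = 3), Mmp3 at 10.2 ± 0.577 and 1.11 ± 0.324 FPKM, and the contractile gene Myl9 at 16.2 ± 0.744 and 4.89 ± 0.804 FPKM. Of the 33 matrix genes 19 fell and 1 rose (21 and 1 adjusted over the list alone; median −0.41, adjusted p = 1.31e-12, adjusted p = 0.157 with an estimated correlation). Wnt and beta-catenin targets fell, 5 of 8 with a median of −0.33 (6 adjusted over the list alone; adjusted p = 2.73e-05, adjusted p = 0.0996 with an estimated correlation; −0.145 with no filter on low values), including the feedback regulators Axin2 (−0.65, SE 0.087) and Nkd2 (−0.84, SE 0.085). Glycolysis and hypoxia genes fell, 13 of 25 against 1 raised (18 and 1 adjusted over the list alone; median −0.38, adjusted p = 3.53e-09, adjusted p = 0.505 with an estimated correlation; −0.24 without library C labelled Son sgRNA in tunicamycin), with Slc16a3 at 41.5 ± 0.967 and 15.2 ± 6.02 FPKM. Interferon genes were lower for 6 of 33 (10 adjusted over the list alone; median −0.15, adjusted p = 0.000314, adjusted p = 0.563 with an estimated correlation; −0.090 with the length trend removed), with the immunoproteasome subunit gene Psmb8 falling from 86.8 ± 1.34 to 33.0 ± 0.799 FPKM. ER chaperones were higher, 6 of 27 raised and 1 lowered (11 and 1 adjusted over the list alone; median 0.16, adjusted p = 2.28e-05, adjusted p = 0.56 with an estimated correlation; 0.10 without control sgRNA library C in tunicamycin), with Hsp90b1 at 897.6 ± 32.0 and 1254 ± 138 FPKM. Ddit3 was higher (0.49, SE 0.117, adjusted p = 0.021), a call lost without library A or C of control sgRNA or library C labelled Son sgRNA, all in tunicamycin. Hspa5 did not pass (0.30, SE 0.106, adjusted p = 0.116), and passed at 0.30 without library C labelled Son sgRNA in DMSO and at 0.39 without library B in tunicamycin. Hoxb9, a patterning gene, rose from 2.06 ± 0.382 to 6.65 ± 0.432 FPKM and Gpnmb from 16.9 ± 0.641 to 30.2 ± 1.76 FPKM. Of 11218 genes 1060 changed, 290 up and 770 down, 48 at least 2-fold. The share raised, 27.4%, was 45.1% under median-ratio scaling, 50.6% under quantile normalization and 46.1% with the length trend removed. Library B labelled Son sgRNA in tunicamycin stood apart, with Rn45s, a ribosomal RNA precursor, listed at 0 and a column sum of 381968. Without it and library C in DMSO 3296 genes changed, 53.4% of them raised, and the medians were −0.38 for the matrix, −0.43 for glycolysis, −0.31 for Wnt targets, −0.13 for interferon and 0.19 for ER chaperone genes. The count was 596, 660 or 595 without control sgRNA library A, B or C in tunicamycin, 2285 without library C labelled Son sgRNA in DMSO and 663 without library C labelled Son sgRNA in tunicamycin.

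Tunicamycin raised ER stress genes in both CRISPRa arms. With control sgRNA Herpud1 rose from 27.6 ± 0.655 to 438.7 ± 22.9 FPKM (log2 fold change 3.94, SE 0.075, adjusted p = 2.91e-11, n = 3), Trib3 from 16.6 ± 1.09 to 183.8 ± 8.34 FPKM, Ddit3 from 43.2 ± 1.64 to 424.4 ± 23.4 FPKM and Hspa5 from 394.1 ± 11.5 to 2352 ± 134 FPKM. In the libraries labelled Son sgRNA Herpud1 rose from 22.0 ± 0.788 to 434.5 ± 49.5 FPKM (4.24, SE 0.075, adjusted p = 1.24e-11) and Hspa5 from 405.4 ± 36.6 to 2899 ± 361 FPKM. Of 39 ATF4 genes 38 rose and 1 fell in each arm (38 and 1 adjusted over the list alone). Their medians were 1.44 (adjusted p = 3.57e-30, adjusted p = 0.157 with an estimated correlation) and 1.57 (adjusted p = 3.02e-30, adjusted p = 0.157 with an estimated correlation). Interferon genes rose with control sgRNA, 26 of 33 with a median of 0.35 (26 adjusted over the list alone; adjusted p = 1.83e-07, adjusted p = 0.379 with an estimated correlation). Among them were the antiviral GTPase Mx1 (3.46 ± 0.136 to 10.7 ± 1.53 FPKM) and Ifi44 (45.9 ± 0.384 to 92.7 ± 8.28 FPKM). In the libraries labelled Son sgRNA 17 of these rose and 4 fell (18 and 5 adjusted over the list alone; median 0.18, adjusted p = 0.0031, adjusted p = 0.659 with an estimated correlation). Under quantile normalization the interferon medians were 0.31 in these libraries and 0.38 with control sgRNA. With control sgRNA 17 of 24 cholesterol synthesis genes fell (18 adjusted over the list alone; median −0.43, adjusted p = 2.56e-11, adjusted p = 0.0996 with an estimated correlation), with Insig1, a sterol sensor, at −0.92 (SE 0.060). Glycolysis and hypoxia genes fell in both arms, 20 of 25 with control sgRNA (22 adjusted over the list alone; median −0.47, adjusted p = 4.42e-10, adjusted p = 0.497 with an estimated correlation) and 22 of 25 in the libraries labelled Son sgRNA (22 adjusted over the list alone; median −0.79, adjusted p = 2.34e-09, adjusted p = 0.505 with an estimated correlation). Cdkn1a fell with control sgRNA, by 0.56 (SE 0.098, adjusted p = 0.000903). With control sgRNA 4295 genes changed, 2714 up and 1581 down, 164 at least 2-fold. In the libraries labelled Son sgRNA 5538 changed, 2549 up and 2989 down, 262 at least 2-fold. The share raised with control sgRNA, 63.2%, was 48.5% under median-ratio scaling, 48.9% under quantile normalization and 48.9% with the length trend removed. There 7000 genes changed without the 2 libraries that stood apart.

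The difference of these 2 tunicamycin responses passed the limma test for 0 of 11218 genes, with 908 at an unadjusted p under 0.05. Hspa5 differed by 0.26 (SE 0.151, adjusted p = 0.605), Trib3 by 0.29 (SE 0.099, adjusted p = 0.6) and Ddit3 by 0.081 (SE 0.165, adjusted p = 0.859). As lists, 39 ATF4 genes lay higher in the libraries labelled Son sgRNA (median 0.15, none called over all genes or adjusted over the list alone, adjusted p = 2.02e-15, adjusted p = 0.346 with an estimated correlation). So did 27 ER chaperones (median 0.12, none called either way, adjusted p = 2.71e-09, adjusted p = 0.379 with an estimated correlation). Interferon genes lay lower (33 genes, median −0.21, none called, 2 adjusted over the list alone, adjusted p = 2.23e-07, adjusted p = 0.379 with an estimated correlation). So did glycolysis and hypoxia genes (25 genes, median −0.35, none called, 2 adjusted over the list alone, adjusted p = 8.51e-06, adjusted p = 0.618 with an estimated correlation). The differences followed transcript length (Spearman 0.55 across genes), and with the length trend removed the medians were 0.25 for the ATF4 list, 0.21 for ER chaperones, −0.086 for interferon and −0.25 for glycolysis genes. In that order they were 0.26, 0.24, −0.090 and −0.16 under quantile normalization. Median-ratio scaling gave 0.19 for ER chaperones and −0.13 for interferon genes, and array weights −0.21 for glycolysis genes. Without the 2 libraries that stood apart the ATF4 list had 0.246 and ER chaperones 0.25, and without library C labelled Son sgRNA in tunicamycin ATF4 genes had 0.078 and glycolysis genes −0.22. The count was 1 without control sgRNA library B in DMSO, 2 without control sgRNA library C in DMSO and 1 without library C labelled Son sgRNA in DMSO. It was 1 without both libraries that stood apart, and 2551 with array weights.

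The effects of Son siRNA and of the Son sgRNA label were set side by side over 10673 genes tested in both systems, which share no library. The cells of these systems differ in Xist, so a difference between the cells cannot be told apart from one between siRNA and label. Across genes, which are not independent replicates, Pearson's r was −0.033 (Spearman −0.009) in DMSO and −0.12 (Spearman −0.085) in tunicamycin. Without library A of control siRNA in DMSO the DMSO value was 0.007, and with array weights 0.011. Fisher's exact test treats the genes as independent, so its p-values do not measure the spread between libraries. In DMSO 224 genes rose in both (194.1 for independent lists, Fisher's exact test odds ratio 1.22, p = 0.013) and 85 fell in both (79.7 for independent lists, odds ratio 1.08, p = 0.492). In opposite directions 173 fell with siRNA and rose with the sgRNA label (157.1 for independent lists, Fisher's exact test odds ratio 1.14, p = 0.144) and 93 did the reverse (98.6 for independent lists, odds ratio 0.93, p = 0.564). In tunicamycin 59 rose in both (79.3 for independent lists, Fisher's exact test odds ratio 0.66, p = 0.00509) and 124 fell in both (137.8 for independent lists, odds ratio 0.87, p = 0.182). There 82 fell with siRNA and rose with the sgRNA label (53.6 for independent lists, Fisher's exact test odds ratio 1.81, p = 2.49e-05) and 215 did the reverse (203.9 for independent lists, odds ratio 1.09, p = 0.34).

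**Figure D3:**
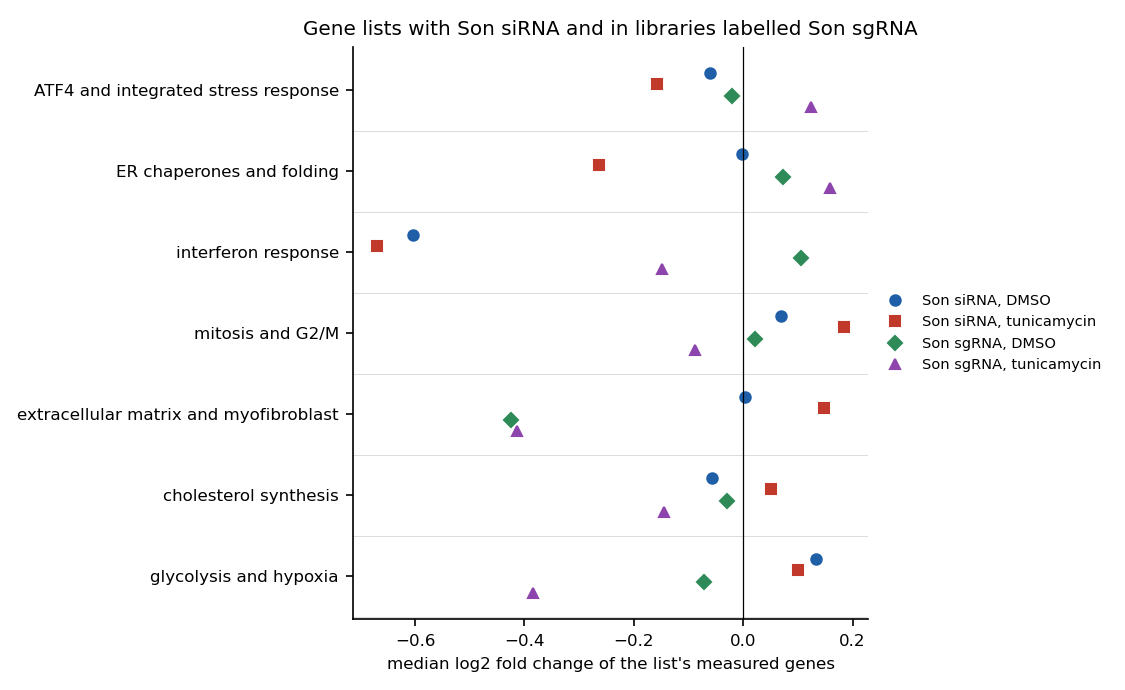
Median log2 fold change of fixed gene lists (horizontal axis) in the comparisons of Son siRNA and of the libraries labelled Son sgRNA with their controls, in DMSO and tunicamycin. The interferon list lies at −0.60 and −0.67 with Son siRNA, and the matrix list at −0.42 and −0.41 in the libraries labelled Son sgRNA.

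Nintedanib, an inhibitor of VEGF, FGF and PDGF receptor tyrosine kinases, raised lysosomal and inflammatory genes over 24 h at 3 µM and lowered interferon genes and the collagen genes Col3a1 and Col1a1. Ptgds, a prostaglandin D synthase (chromosome 2, 25466709 to 25470046), rose from 1.23 ± 0.243 to 124.6 ± 12.04 TPM (log2 fold change 5.81, SE 0.148, adjusted p = 3.12e-13, n = 3), and Gpnmb (chromosome 6, 49036546 to 49070929) from 8.12 ± 1.12 to 132.3 ± 2.82 TPM. Lysosomal enzyme genes such as Hexa (113.0 ± 5.10 to 486.8 ± 10.2 TPM), Ctsa and Tpp1 rose. Of 44 autophagy and lysosome genes 36 rose and 4 fell (36 and 4 adjusted over the list alone; median 0.74, adjusted p = 1.81e-12, adjusted p = 0.269 with an estimated correlation). Of 21 inflammatory and NF-kappaB genes 20 rose (20 adjusted over the list alone; median 0.79, adjusted p = 9e-08, adjusted p = 0.159 with an estimated correlation), with the acute phase genes Saa3 at 19.4 ± 4.72 and Lcn2 at 6.11 ± 0.457 TPM. The 3 measured macrophage and leukocyte markers rose as well (3 adjusted over the list alone; median 1.19, adjusted p = 0.0299, adjusted p = 0.265 with an estimated correlation). Immediate early genes rose, 17 of 24 (17 adjusted over the list alone; median 0.63, adjusted p = 0.00084, adjusted p = 0.394 with an estimated correlation), among them Egr1 (75.1 ± 5.29 to 196.5 ± 6.12 TPM). Col3a1 fell from 541.4 ± 20.97 to 133.6 ± 2.92 TPM and Col1a1 from 2278 ± 46.6 to 1292 ± 48.9 TPM. Interferon genes fell, 27 of 33 against 4 raised (27 and 4 adjusted over the list alone; median −0.65, adjusted p = 2.91e-09, adjusted p = 0.345 with an estimated correlation), with Isg15 going from 483.5 ± 42.3 to 195.4 ± 9.84 TPM. Mitotic genes fell, 27 of 28 (28 adjusted over the list alone; median −0.42, adjusted p = 1.5e-13, adjusted p = 0.179 with an estimated correlation). Cytosolic ribosomal protein genes fell too, 59 of 60 (60 adjusted over the list alone; median −0.33, adjusted p = 7.75e-24, adjusted p = 0.277 with an estimated correlation; −0.21 under quantile normalization). Hspa5 fell by 0.74 on the log2 scale (SE 0.037) to 597.4 ± 8.79 TPM and Asns, an ATF4 target that makes asparagine, from 144.9 ± 2.80 to 74.7 ± 26.5 TPM. Of 12132 genes 6845 changed, 4163 up and 2682 down, 554 at least 2-fold. The share raised, 60.8%, was 45.1% under median-ratio scaling, 41.1% under quantile normalization and 45.8% with the length trend removed. Quantile normalization moved the median of all genes from 0.040 to −0.066. In nintedanib library 1 the deviations from the group mean followed transcript length (Spearman −0.59, 14.5% of their variance).

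Ponatinib, an inhibitor of BCR-ABL and other tyrosine kinases, lowered glycolysis and cholesterol synthesis genes at 1 µM and raised lysosomal and ATF4 genes. Ldha, lactate dehydrogenase, fell from 3038 ± 67.9 to 916.6 ± 139 TPM (log2 fold change −1.74, SE 0.089, adjusted p = 4.42e-10, n = 3) and Slc16a3 from 255.2 ± 0.860 to 44.1 ± 13.4 TPM. Of 25 glycolysis and hypoxia genes 23 fell and 2 rose (23 and 2 adjusted over the list alone; median −1.28, adjusted p = 2.99e-15, adjusted p = 0.245 with an estimated correlation). Hmgcs1, an enzyme of cholesterol synthesis (chromosome 13, 119690379 to 119708260), fell from 338.0 ± 15.6 to 91.7 ± 2.10 TPM. Of 25 cholesterol synthesis genes 22 fell (22 adjusted over the list alone; median −1.21, adjusted p = 4.18e-19, adjusted p = 0.159 with an estimated correlation). ATF4 genes rose, 33 of 40 against 2 lowered (34 and 3 adjusted over the list alone; median 0.73, adjusted p = 5.97e-06, adjusted p = 0.389 with an estimated correlation). Ddit3 stood at 136.0 ± 4.51 against 52.3 ± 3.52 TPM and Trib3 at 90.7 ± 3.80 against 26.8 ± 2.06 TPM, while Hspa5 fell to 577.8 ± 12.1 TPM. Autophagy and lysosome genes rose, 38 of 44 against 3 lowered (40 and 3 adjusted over the list alone; median 0.68, adjusted p = 1.21e-10, adjusted p = 0.277 with an estimated correlation). Immediate early genes fell, 16 of 24 against 2 raised (16 and 2 adjusted over the list alone; median −0.65, adjusted p = 8.34e-07, adjusted p = 0.277 with an estimated correlation), such as Jun (36.4 ± 1.43 to 10.8 ± 0.420 TPM) and Dusp1 (26.1 ± 0.491 to 9.27 ± 1.68 TPM). Of the mitotic genes 27 of 28 fell and 1 rose (27 and 1 adjusted over the list alone; median −0.43, adjusted p = 1.55e-13, adjusted p = 0.179 with an estimated correlation). Of the proteasome genes 31 of 36 fell and 2 rose (31 and 2 adjusted over the list alone; median −0.31, adjusted p = 4.64e-14, adjusted p = 0.159 with an estimated correlation). Cox6a2, a muscle-type cytochrome oxidase subunit, rose to 23.3 ± 1.86 TPM and the interleukin 33 receptor gene Il1rl1 fell from 45.2 ± 5.31 to 3.48 ± 0.163 TPM. The clock output gene Dbp rose from 15.1 ± 0.927 to 54.9 ± 1.78 TPM as Arntl fell from 15.01 ± 0.898 to 8.09 ± 0.426 TPM. Of 12132 genes 7583 changed, 4987 up and 2596 down, 617 at least 2-fold. The share raised, 65.8%, was 48.2% under median-ratio scaling, 48.4% under quantile normalization and 47.9% with the length trend removed. Median-ratio scaling moved the median of all genes from 0.097 to −0.013.

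Proflavine, an acridine dye that intercalates into DNA, raised interferon, inflammatory and immediate early genes at 3 µM and lowered cholesterol synthesis and matrix genes. Cxcl10, an interferon-induced chemokine (chromosome 5, 92346638 to 92348889), rose from 279.0 ± 18.3 to 1734 ± 61.9 TPM (log2 fold change 2.63, SE 0.084, adjusted p = 2.58e-12, n = 3) and Oasl1 from 47.2 ± 3.92 to 263.0 ± 13.9 TPM. Of 33 interferon genes 29 rose and 2 fell (29 and 2 adjusted over the list alone; median 1.15, adjusted p = 1.02e-12, adjusted p = 0.277 with an estimated correlation). Il6 stood at 6.42 ± 0.822 against 0.294 ± 0.0676 TPM and the chemokine gene Ccl2 at 1620 ± 36.3 against 385.2 ± 16.8 TPM. Of 21 inflammatory genes 18 rose and 1 fell (18 and 1 adjusted over the list alone; median 0.82, adjusted p = 5.88e-07, adjusted p = 0.159 with an estimated correlation; 1.29 with a pseudocount of 0.1). The MAPK phosphatase gene Dusp4 (1.22 ± 0.179 to 24.1 ± 2.71 TPM), the ETS factor gene Etv4 (4.62 ± 0.402 to 46.6 ± 3.37 TPM) and the cyclin gene Ccnd1 (8.63 ± 0.0354 to 67.0 ± 3.79 TPM) rose, as did 16 of 24 immediate early genes against 1 lowered (17 and 1 adjusted over the list alone; median 0.84, adjusted p = 1.22e-05, adjusted p = 0.319 with an estimated correlation). The cytokine gene Il24 was listed at 0 in every DMSO library and stood at 13.3 ± 3.12 TPM. All 25 cholesterol synthesis genes fell (25 adjusted over the list alone; median −1.24, adjusted p = 6.84e-11, adjusted p = 0.245 with an estimated correlation), with Mvd at 140.0 ± 9.43 and 43.9 ± 2.57 TPM. Col3a1 fell from 541.4 ± 20.97 to 57.4 ± 3.97 TPM and Col1a1 to 780.8 ± 34.1 TPM. Of 35 matrix genes 25 fell and 9 rose (25 and 9 adjusted over the list alone; median −0.79, adjusted p = 0.00156, adjusted p = 0.418 with an estimated correlation). ER chaperones fell, 25 of 27 against 1 raised (25 and 1 adjusted over the list alone; median −0.43, adjusted p = 2.94e-06, adjusted p = 0.265 with an estimated correlation). Pdia4 stood at 278.4 ± 4.85 and 148.6 ± 4.26 TPM, and Xbp1 fell from 66.8 ± 1.89 to 28.3 ± 2.14 TPM while Ddit3 rose to 76.2 ± 2.60 TPM. Cytosolic ribosomal protein genes rose, 49 of 60 against 1 lowered (50 and 1 adjusted over the list alone; median 0.27, adjusted p = 4.82e-12, adjusted p = 0.386 with an estimated correlation; 0.17 under quantile normalization). Of 12132 genes 8510 changed, 3367 up and 5143 down, 954 at least 2-fold. The share raised, 39.6%, was 50.5% with the length trend removed.

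Pyrvinium, an anthelmintic dye known to inhibit mitochondrial respiration, gave the largest number of changed genes of the 4 drugs in these fits, at 1 µM. Car6, a carbonic anhydrase (chromosome 4, 150187015 to 150201332), stood at 174.1 ± 9.70 against 0.188 ± 0.151 TPM (log2 fold change 7.21, SE 0.138, adjusted p = 2.3e-15, n = 3), and Avil, Cox6a2 and Lcn2 stood at 133.5 ± 17.1, 109.1 ± 3.35 and 94.3 ± 13.9 TPM against less than 1 TPM in DMSO. ATF4 genes rose, 38 of 40 against 1 lowered (38 and 1 adjusted over the list alone; median 1.71, adjusted p = 1.96e-14, adjusted p = 0.253 with an estimated correlation). Ddit3 rose from 52.3 ± 3.52 to 779.0 ± 49.5 TPM, Trib3 from 26.8 ± 2.06 to 330.5 ± 22.6 TPM and Cth, the enzyme that makes cysteine, from 9.97 ± 0.8294 to 292.9 ± 13.7 TPM. Hspa5 rose 1.49-fold. All 25 cholesterol synthesis genes fell (25 adjusted over the list alone; median −2.35, adjusted p = 2.17e-13, adjusted p = 0.179 with an estimated correlation). Insig1 (chromosome 5, 28071363 to 28078662) fell from 258.3 ± 7.98 to 16.8 ± 3.09 TPM. Glycolysis and hypoxia genes fell, 22 of 25 against 3 raised (22 and 3 adjusted over the list alone; median −1.77, adjusted p = 1.69e-07, adjusted p = 0.345 with an estimated correlation). Col3a1 fell to 22.2 ± 3.59 TPM, Vim, the mesenchymal intermediate filament gene, from 2255 ± 47.4 to 369.7 ± 39.6 TPM. Of 35 matrix genes 30 fell against 3 raised (30 and 3 adjusted over the list alone; median −1.31, adjusted p = 9.9e-07, adjusted p = 0.277 with an estimated correlation; −0.81 with no filter on low values). All 9 measured fibroblast markers fell as well (9 adjusted over the list alone; median −1.49, adjusted p = 0.000112, adjusted p = 0.159 with an estimated correlation). DNA replication genes fell, 26 of 30 against 1 raised (26 and 1 adjusted over the list alone; median −0.56, adjusted p = 6e-07, adjusted p = 0.259 with an estimated correlation). So did all 28 mitotic genes (28 adjusted over the list alone; median −0.57, adjusted p = 1.63e-07, adjusted p = 0.277 with an estimated correlation). Splicing factors of the SR family fell, 9 of 12 with a median of −0.63 (9 adjusted over the list alone; adjusted p = 0.00207, adjusted p = 0.419 with an estimated correlation), including Srsf3 (311.1 ± 2.91 to 121.2 ± 21.9 TPM) and Srsf1 (191.4 ± 3.71 to 83.0 ± 10.9 TPM). Interferon genes rose, 27 of 33 against 2 lowered (27 and 2 adjusted over the list alone; median 0.91, adjusted p = 2e-07, adjusted p = 0.386 with an estimated correlation), with Ifi44 going from 36.2 ± 3.79 to 372.2 ± 21.02 TPM. Ribosomal protein genes rose, 54 of 60 against 1 lowered (54 and 1 adjusted over the list alone; median 0.52, adjusted p = 1.96e-14, adjusted p = 0.345 with an estimated correlation). Of 12132 genes 9380 changed, 4435 up and 4945 down, 1766 at least 2-fold.

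**Figure D4:**
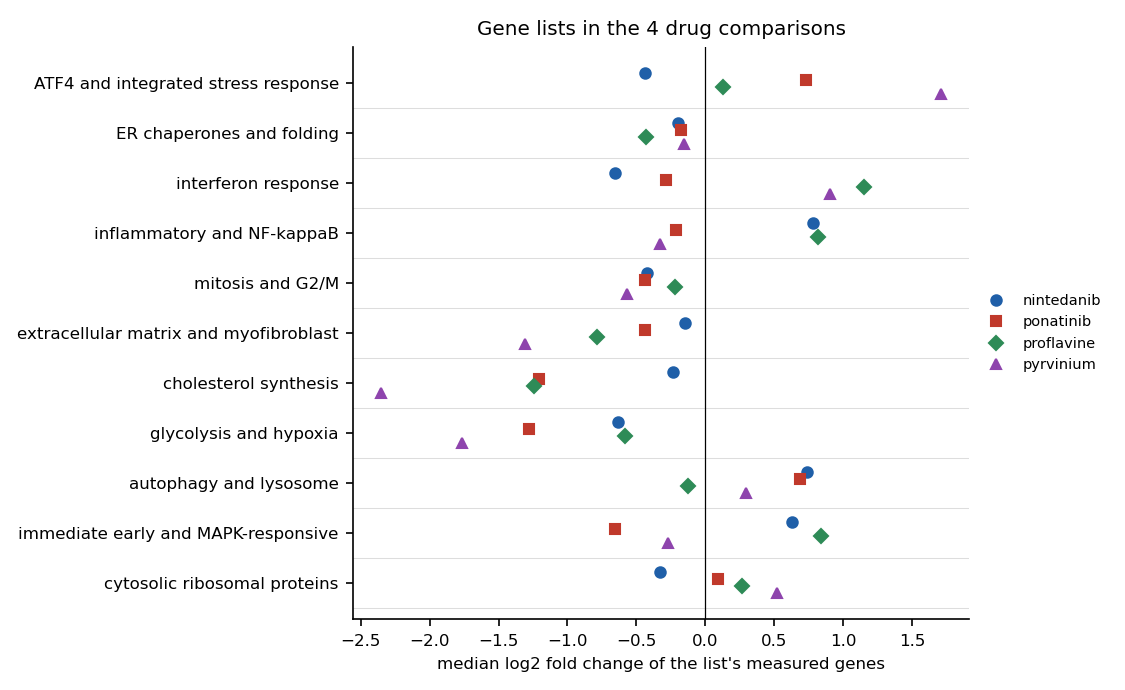
Median log2 fold change of fixed gene lists (horizontal axis) for each drug against DMSO. Cholesterol synthesis genes lie at −1.21 with ponatinib, −1.24 with proflavine and −2.35 with pyrvinium.

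The 4 drugs were compared with each other, at the doses of 3 µM for nintedanib and proflavine and 1 µM for ponatinib and pyrvinium. Raised in all 4 were 505 genes and lowered in all 4 were 493, while 492 of 12132 were called by none. Nintedanib and ponatinib shared 2722 raised and 1271 lowered genes (1711 and 573.9 for independent lists), with r = 0.52 across genes. All the comparisons use the same 3 DMSO libraries, which alone gave r = 0.50 between unchanged groups in simulation and 0 genes called in both. The covariance, to which shared controls add a fixed amount, was 0.115 against 0.0077 simulated. For ponatinib and proflavine r was −0.12 (covariance −0.034 against 0.0077 simulated), with 3645 genes called in opposite directions. Proflavine and pyrvinium shared 1880 raised and 2793 lowered genes (1231 and 2096 for independent lists; r = 0.36, covariance 0.168 against 0.0077 simulated), and ponatinib and pyrvinium 2371 and 1593 (1823 and 1058 for independent lists; r = 0.36, covariance 0.141 against 0.0077 simulated), with 2178 and 2179 genes called in opposite directions. For nintedanib r was 0.17 with proflavine and 0.18 with pyrvinium (covariance 0.046 and 0.068), with 2457 and 2373 genes called in opposite directions. With 3 controls the controls could not be divided into groups of at least 2, so part of any excess may come from the shared controls.

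Genes that responded to Son siRNA or to the Son sgRNA label were followed in the drug comparisons, as sets of up to 200 genes. Of the 16 tests, 5 passed with the preset correlation and 0 with an estimated one (camera, adjusted p = 0.98 in each). The set raised in the libraries labelled Son sgRNA lay higher with nintedanib (104 of 180 measured genes raised and 27 lowered, median 0.26, adjusted p = 0.000332) and with ponatinib (109 raised and 27 lowered, median 0.26, adjusted p = 0.00337, a call lost with array weights at a median of 0.17 and adjusted p = 0.0942 and without the 2 libraries that stood apart at 0.16 and adjusted p = 0.0787). The set lowered in those libraries lay lower with pyrvinium (44 of 181 raised and 115 lowered, median −0.56, adjusted p = 0.000332) and with ponatinib (75 raised and 73 lowered, median −0.023 against 0.097 for all genes, adjusted p = 0.0158), the latter call being lost without library A (median 0.012, adjusted p = 0.079) or C (0.026, adjusted p = 0.087) labelled Son sgRNA in DMSO and under other settings. With proflavine the lowered set did not pass (45 of 181 raised and 105 lowered, median −0.36, adjusted p = 0.0595) but was called lower under 7 alternatives. Among these the adjusted p was lowest with a mean of at least 5 (median −0.38, camera adjusted p = 0.00157). The median was lowest without library C labelled Son sgRNA in tunicamycin (−0.413, camera adjusted p = 0.021). The set raised with Son siRNA lay lower with proflavine (28 of 189 raised and 102 lowered, median −0.20, adjusted p = 0.00644), a call lost without library B of Son siRNA in DMSO (median −0.18, adjusted p = 0.0504). With sets of at most 50 genes none of the 16 tests passed (lowest adjusted p = 0.0575), and the last set (median −0.039) and the lowered set with ponatinib (0.31) then lay above all genes. Across genes the drug effects had r of −0.19 (proflavine), −0.12 (pyrvinium), −0.007 (nintedanib) and 0.002 (ponatinib) with the Son siRNA effect in DMSO, over 10293 genes. With the effect of the Son sgRNA label in DMSO r was 0.086 (proflavine), 0.11 (pyrvinium), 0.048 (nintedanib) and 0.12 (ponatinib), over 10524 genes.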

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

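The tests of Son with the length trend removed and of exchanged arms and both tests of the weaker ER stress response were chosen only after the result was seen.

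Son RNA was not higher in the libraries labelled Son sgRNA, with log2 fold changes of −0.20 in DMSO and −0.059 in tunicamycin. With the length trend removed Son stood at −0.058 in DMSO (SE 0.055, reaching 0.053 at 2 SE above) and −0.020 in tunicamycin, which argues against a loss of long transcripts as the reason. Over the 200 genes of smallest p found without it, 0 of 12 libraries lay nearer to the other sgRNA arm, which argues against single libraries exchanged between the arms. An exchange of the whole arms could hide a rise of up to 0.515 in the main fit in DMSO (0.169 with the length trend removed), and array weights called Son lower there (−0.089, adjusted p = 0.03), so it stays open beside an activation that may have been weak, brief or absent, with no biological explanation tested. Length bias and the share of abundant genes were also tried as reasons why library C in DMSO and library B in tunicamycin stood apart, gave 36.4% and 10.0% for library C and 6.5% and 9.6% for library B (33.2% and 8.5% for library A beside C), decided nothing and were dropped, and a test of their depth was faulty and was not run again as planned.

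Interferon genes were lower with Son siRNA, with a list median of −0.60 in DMSO. With any 1 library left out the median came no nearer to 0 than −0.546, and with the length trend removed it was −0.615, so the tables argue against a single library and against length bias. An interferon response raised by the control siRNA could lower the genes in the same way. In DMSO the list had a median log2 ratio of −0.208 between control siRNA and control sgRNA libraries, with 13 of 33 genes higher with control siRNA. This cannot be told apart from a difference of the cells, since they differ in Xist, so that explanation stays open beside an effect of lower Son.

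The difference of tunicamycin responses with Son siRNA passed the test for 183 genes, and ER chaperones had a list median of −0.242. Their response with Son siRNA had a median ratio of 0.837 to that with control siRNA (18 genes, all 18 below 1), against 0.874 among 1162 other genes that responded (difference −0.037, SE 0.021) and 0.941 among 39 ATF4 genes (30 below 1). A damping shared by most genes that responded may therefore account for the lower chaperone response. It was not uniform, as the ratio of the ATF4 genes lay nearer to 1. The gap between the ATF4 genes and the chaperones was not tested. Without control siRNA library D in tunicamycin, which held 10 of the outlying values of the siRNA system, the list median was −0.151 and the ratios were 0.888 and 0.938, so part of the difference may rest on that library and the test left this open. The count without it was 233, and the share of it due to Son stays untested.

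Among 252 groups of 4 libraries (63 genes), 24 held a library far from the others, while chance picks out about 1 in 20 groups. Of these, 10 were control siRNA library D in tunicamycin. In that library Herpud1 stood at 849.6 FPKM (others 680.6 to 701.4), Creld2 at 648.7 (438.8 to 469.3), Sdf2l1 at 377.9 (258 to 270.0), Slc7a5 at 216.7 (170.9 to 173.8), Derl1 at 115.3 (95.6 to 97.0), Gadd45a at 98.2 (84.2 to 85.9) and Ero1l at 84.0 (69 to 71.4). Mtm1 stood at 11.7 (8.40 to 8.67), Angptl2 at 11.6 (18.3 to 19.2) and Vldlr at 11.2 (9.40 to 9.57). With control siRNA in DMSO, library A had Angptl2 at 60.9, Sdf2l1 at 26.1, Gdnf at 8.56 and Tnfrsf9 at 8.48, library B Mx1 at 5.47, library C Pck2 at 17.5 and library D Prr3 at 11.1 FPKM. Control siRNA library C in tunicamycin had Arntl at 12.1 FPKM. With Son siRNA in DMSO, library A had Dnajb9 at 5.90 and library B Atf4 at 160.3 and Pycr1 at 1.05 FPKM. With Son siRNA in tunicamycin, library C had Ctgf at 12.8 and library D Gdnf at 8.17 and S100a4 at 410.7 FPKM.

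Genes whose tunicamycin response differed with Son siRNA by the interaction test were, with log2 differences, Pycr1 (−0.557), Bcat2 (−0.510), Mtm1 (−0.493), Ero1lb (−0.474), Dnajb9 (−0.467), Ero1l (−0.427), Syvn1 (−0.423), Herpud1 (−0.382), Vldlr (−0.363), Creld1 (−0.327), Derl1 (−0.269) and Nupr1 (−0.267). Differences were positive for Ccnd1 (0.756), Oaf (0.544), Nid1 (0.526) and Gdnf (0.440). Ccnd1, Oaf and Nid1 fell less in tunicamycin with Son siRNA, while Gdnf fell with control siRNA and rose with Son siRNA. Of the 16 fits that left out 1 library, 14 lost the call of Pycr1, 11 those of Derl1 and of Vldlr, 9 those of Dnajb9 and of Mtm1, 8 those of Ccnd1, Ero1l, Herpud1 and Syvn1, 6 that of Ero1lb, 5 that of Nid1 and 1 that of Creld1. List medians differed for ER translocation and degradation (−0.119), ATF4 (−0.099), mitosis (0.135) and matrix genes (0.124) with Son siRNA, none of which held with an estimated correlation (lowest adjusted p = 0.432 over all lists). Without control siRNA library D in tunicamycin the ATF4 median was −0.031 and that of matrix genes 0.080, which was 0.076 with array weights. In the libraries labelled Son sgRNA they differed for ATF4 (0.15), ER chaperones (0.115), interferon (−0.208) and glycolysis genes (−0.351), again with none that held (lowest adjusted p = 0.346 with an estimated correlation). Tunicamycin moved Cdkn1a by −0.558 with control sgRNA and by 0.788 with control siRNA, with no overlap of the libraries in either, and this difference between the systems was not tested.

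The same libraries were also split into other groups of the same sizes. For the siRNA system 1 of 35 splits, the real one, reached each of the counts of 3923, 5552, 7504 and 7314 genes, and the highest others were 0, 1, 1 and 0. A chance division of these libraries is thus unlikely at 1 in 35, the smallest share that 35 splits can give. A difference between single cultures could give the same shares, since the labels do not state separate cultures. For the 183 genes of the interaction 3 of 100 splits did, the real one included, and the others called 2780 and 909 genes. Splits that mix the arms put the effect of Son siRNA itself into the difference or into the spread, so they decide nothing here. With the mean effect of the arm taken out of each gene first, 1 of 100 splits, the real one, reached 183 and the highest other called 1. A chance division of these libraries is thus unlikely at 1 in 100, with the same limit on cultures. The splits also leave open an effect of single libraries, since the count fell to 24 without library B of Son siRNA in DMSO. For the interaction in the CRISPRa system the real count was 0, which all 100 of 100 splits reach whatever the data (highest 181), so the splits say nothing about chance there. For groups of 3 libraries the 10 splits are too few for a share under 0.05. There the real counts were 1615, 1060, 4295 and 5538 in the CRISPRa system (highest others 0, 0, 2 and 0) and 6845, 7583, 8510 and 9380 for nintedanib, ponatinib, proflavine and pyrvinium (highest others 2, 0, 1 and 0), each reached by 1 of 10.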

How the results depend on the processing

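Apart from settings that left out 1 library, single genes, lists and sets gave the same direction and side of the threshold in 4548 cases, lost the call in 48, gained one in 37, moved without a test in 7 and turned in 5. With 1 library left out the numbers were 6496 kept, 153 lost, 14 gained and 12 turned. Where results changed, the cause was not tested unless stated. Depth is known only relative to other libraries in the FPKM table and not at all in the TPM table, so no limit of detection can be given.

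The 183 genes of the Son siRNA interaction became 62 with no filter on low values, 313 under quantile normalization, 386 with array weights, 285 with a block on the column letter and 289 with the length trend removed. In the CRISPRa system array weights gave 7471 genes for the Son sgRNA label in DMSO, 4187 in tunicamycin, 7716 for tunicamycin with control sgRNA, 8786 with Son sgRNA and 2551 for their difference, and Son in DMSO passed at −0.089 (adjusted p = 0.03). With only the 2 groups compared the counts were 581 for the label in DMSO, 7260 for tunicamycin with control sgRNA and 3241 with Son sgRNA. With a mean of at least 5 the label gave 693 genes in tunicamycin, where fewer genes were tested. With the length trend removed the label gave 2534 genes in DMSO and 2182 in tunicamycin. Without the 2 libraries that stood apart it gave 3236 and 3296, tunicamycin with control sgRNA 7000 and the difference of responses 1. The settings all lines, length trend, block on the letter and without the 2 libraries were chosen after seeing the data.

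Son with nintedanib (−0.226) missed the threshold with no filter (adjusted p = 0.0758), no trend (adjusted p = 0.0577), a replicate block (adjusted p = 0.05) and only the 2 groups compared (adjusted p = 0.094). Son with ponatinib passed it under median-ratio scaling (−0.249), quantile normalization (−0.181), array weights (−0.130), only the 2 groups compared (−0.132) and with the length trend removed (−0.239), and Son with proflavine turned to 0.108 with the length trend removed and passed there (adjusted p = 0.00588). The 53, 78 and 71 list calls of the siRNA, CRISPRa and drug systems became 0, 0 and 0 with an estimated correlation. The correlation of the ponatinib and Son siRNA effects turned to −0.011 with pseudocount 0.1 and −0.016 under quantile normalization, that of nintedanib to 0.008 with a mean of at least 5, and that of the siRNA and sgRNA effects in DMSO to 0.011 with array weights. The 5 called Son-responsive sets became 3 with array weights and 0 with sets of at most 50 genes, where the set lowered with the sgRNA label stood at 0.312 with ponatinib and the set raised by siRNA at −0.039 with proflavine, above all genes.

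With each library left out in turn, counts ranged from 3203 to 4374 (Son siRNA in DMSO), 5036 to 5601 (in tunicamycin), 7155 to 7567 (tunicamycin with control siRNA), 6919 to 7430 (with Son siRNA) and 24 to 322 (their difference). In the CRISPRa system they ranged from 739 to 2640 (label in DMSO), 595 to 2285 (in tunicamycin), 3185 to 6163 (tunicamycin with control sgRNA), 4492 to 5952 (with Son sgRNA) and 0 to 2 (their difference). For nintedanib, ponatinib, proflavine and pyrvinium they ranged from 6192 to 7442, 6914 to 8050, 7939 to 8928 and 8924 to 9656. Son ranged from −0.995 to −0.947 and −1.211 to −1.132 with siRNA, −0.369 to 0.022 and −0.134 to 0.047 with the sgRNA label, and −0.303 to −0.091, −0.159 to −0.105, −0.018 to 0.011 and −0.544 to −0.425 with the drugs in that order. List calls ranged from 50 to 59, 72 to 82 and 69 to 71, called sets from 4 to 6, and genes shared by the 4 drugs from 847 to 1102. The correlations ranged from −0.070 to 0.007 (siRNA and sgRNA in DMSO), −0.134 to −0.070 (in tunicamycin), −0.030 to 0.003 (nintedanib and Son siRNA) and −0.017 to 0.016 (ponatinib and Son siRNA).

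The FPKM columns of the siRNA and CRISPRa systems carry letters and not the numbers of the labels, so the replicate block was fitted there on the letter, which need not be the number. The 24 pairs of siRNA libraries with the same letter had correlations of −0.189 to 0.174 (mean 0.013 against −0.004 for other pairs, 4 of 16 libraries closest to their own letter), and the 18 CRISPRa pairs −0.223 to 0.182 (mean −0.017 against 0.011, 4 of 12 libraries). With this block the difference of responses with Son siRNA was called for Ddit3 (−0.364, adjusted p = 0.049) and Son (−0.206, adjusted p = 0.0403). Hspa5 (−0.199, adjusted p = 0.0227) and Malat1 (−0.312, adjusted p = 0.0105) were called with Son siRNA in DMSO, and Col1a1 lost its call for the label in tunicamycin (−0.326, adjusted p = 0.0691). For the drugs the 30 pairs of libraries with the same number had correlations of −0.067 to 0.147 (mean 0.017 against −0.008 for other pairs), and 5 of 15 libraries lay closest to their own number.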

Other observations

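The test of the correlation with the length trend removed was chosen only after the result was seen.

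A hypothesis was that lower Son and the Son sgRNA label move the tunicamycin response in opposite directions. Across 10673 genes, which are not independent replicates, the differences of responses in the siRNA and CRISPRa systems had a Pearson r of −0.320 (−0.351 to −0.275 with 1 library left out, leave-one-out error 0.090), as the hypothesis needs. It was −0.298 without the 2 libraries that stood apart and −0.328 with the length trend removed, which argues against length bias as the whole cause. Son RNA was not higher with the Son sgRNA label. There 0 genes passed the limma test of the difference (908 at an unadjusted p under 0.05). A response weaker or stronger throughout in 1 arm can give r of either sign, so r decides nothing about Son. The cells also differ in Xist.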
